A study of Gallus gallus with 16 samples.

How the data were processed

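The study mapped histone modifications by ChIP-seq in micromass cultures of chick limb bud mesenchyme that carried an empty RCAS-BP(A) virus. Per the labels' protocols, chromatin of 8 cultures was pooled, fixed with 1% formaldehyde for 10 min and sheared to 200 to 500 bp, 10 µg of chromatin were precipitated with 4 µg of antibody, and 50-bp single-end reads were sequenced. Of 16 libraries, 10 carried peak lists (5 marks, 2 replicates each). The 6 inputs, 3 per replicate number, were not analysed here.

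The submitters' processing notes name BWA, SAMtools, MACS2 and bedtools, without versions, and the galGal4 build. How inputs were matched to libraries and which options were used is not given in the sources used here. The authors deposited a broad and a narrow peak list for each library, so peaks were called per library and not on pooled replicates. The deposited lists have no header and follow the MACS2 layout. Their columns hold the peak's position, a score (an integer from 10 times a −log10 value), a ratio (fold enrichment of the ChIP signal over its background), and −log10 of the p-value and of the q-value, all as the authors' peak caller gave them. Fold, score and −log10 values belong to single peaks and were used only to describe, rank or filter peaks within a list. The lowest deposited −log10 p was 1.00 in the broad lists and 2.00 in the narrow lists, so the broad lists are permissive (p of 0.1, against 0.01). Minimum widths ran from 123 to 145 bp, the same in both lists of a library. Gaps of up to 4 times that width had been joined in broad lists and gaps of up to 50 bp in narrow lists. No overlapping or duplicate peaks were present. Read numbers are unknown, so a longer list can reflect deeper sequencing or a better antibody, and counts and covered lengths are not corrected for depth.

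Broad peaks as deposited were the main input. For each library the number of peaks, the covered base pairs, the median width, the peaks of 10 kb or more and the share of covered length on microchromosomes were computed; that share used macrochromosomes (1 to 5, Z), intermediate chromosomes (6 to 10) and microchromosomes (11 to 28; the scheme includes 32, on which there were no peaks) and left out unplaced sequence, W and LGE64. Marks were compared with a one-way F statistic on log10 values (percentages for the microchromosome share), with a two-sided exact permutation over the 945 divisions of 10 libraries into 5 pairs. The smallest p this allows is 0.00106, and a pair of marks alone, 2 libraries against 2, cannot go below 0.333 in an exact permutation test. Replicate agreement was the mean Jaccard index of same-mark pairs minus that of other pairs, over the same 945 pairings.

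Overlap of marks was measured in bins of 50 bp on assembled chromosomes within each replicate number. Expected values came from 1000 random circular shifts of one mark along each chromosome, whose length was taken as the furthest peak end in any list. The larger p of both replicates was used, set to 1 where replicates went opposite ways, with Benjamini-Hochberg adjustment over the 10 pairs. Shifts of whole chromosomes do not keep regional density, so local shifts of 0.1 to 1 Mb were also run, and these are the reference for domains of 10 kb or more. Peaks overlapped where at least 1 bin or 1 bp was shared. A widest domain is a locus where peaks of both replicates overlap, ranked by the mean width of the widest peak of each replicate. Its coverage by other marks is measured over the stretch that both replicates share and is the mean of both replicates. The rule for regions, the 10 widest per mark, and the tests were fixed before the data were examined. The sorting of peaks by H3K27ac and H3K27me3, the summit profiles, the wide domains as a class and chromosome Z were added afterwards. Positions are 1-based.

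The planned results on transcription start sites (share of peaks at a start site, H3K4me3 with H3K27me3 at the same start site, and 13 gene lists by mark, among them muscle, blood and endothelium, surface epithelium and neural markers) need an annotation of galGal4. The gene table at hand belongs to another build, GRCg7b, so none of its coordinates were used, those results were not run, and no gene is named. H3K4me3 peaks took the place of promoters, and distal H3K4me1 peaks were those that do not overlap H3K4me3.

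The tests were tested on simulated data. For 60 pairs of independent simulated peak sets the shift test gave p under 0.05 in 6.67% for shared base pairs and in 10% for overlapped peaks, so a p near the threshold for overlapped peaks is weak. All of 20 sets with 20% of peaks planted were detected. The simulated sets were smaller than the real lists and placed at random by chromosome length, without the regional density of real peaks. These rates therefore do not show how often the shift test errs on the real lists. The F permutation gave p under 0.05 in 6% of 200 simulations with no effect. Alternatives were narrow peaks, peaks with −log10 q of at least 5, the strongest peaks in equal number, assembled chromosomes, each replicate left out, a replicate block, an overlap of 50% of the peak, a distance of 10 kb from H3K4me3, domains of 20 kb or more, local shifts, and the percent of peaks overlapped. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.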

Results

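Chromatin immunoprecipitation with sequencing (ChIP-seq) mapped 5 histone modifications in chick limb mesenchyme. Mesenchymal cells of limb buds from embryos at day 4.5 were plated as droplets of 10 µL at high density (micromass culture, in which limb bud cells condense and form cartilage), infected with an empty RCAS-BP(A) retrovirus and grown for 5 days. The empty virus is the control of a study of transcription factors linked to connective tissue, and these libraries describe the chromatin of the control cultures. H3K4me1, H3K4me2, H3K4me3, H3K27ac and H3K27me3 were each measured in 2 replicates, and each chromatin preparation pooled 8 cultures. H3K4me3 typically lies at promoters, H3K4me1 at enhancers and around promoters, H3K27ac at active promoters and enhancers, and H3K27me3 is the mark of Polycomb repression. The 10 libraries carried between 24180 and 184423 broad peaks and between 31812 and 205158 narrow peaks. Peak lists give no read number, so the depth of each library is unknown, and 6 input libraries were not analysed here. The labels give replicate numbers without saying that the replicates came from separate embryos. The p-values of permutations over libraries therefore measure the spread between these libraries, which may be technical. The p-values from circular shifts were computed within each replicate number. They concern the positions of peaks and measure no spread between libraries. All positions are galGal4, and no gene annotation of that build was used here.

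The first comparison asked how much of the genome each mark occupied and in what form. H3K4me1 occupied the most sequence, with 210 Mb ± 18.4 (SD, n = 2) in broad peaks, and H3K4me3 the least, with 36.4 Mb ± 2.68 (SD, n = 2). H3K27ac covered 195 Mb ± 31.3, H3K27me3 175 Mb ± 13.2 and H3K4me2 89.1 Mb ± 1.504 (SD, n = 2 each). The replicates of H3K4me1 and H3K27ac overlapped in covered length, as did those of H3K27ac and H3K27me3, whereas H3K4me2 and H3K4me3 lay apart from all other marks by more than the spread between replicates. Among the 5 marks H3K4me3 had the widest typical peak, with a median of 991 bp ± 61.5 (SD, n = 2), and H3K27ac the narrowest, with 599 bp ± 1.41 (SD, n = 2). The medians were 823 bp ± 4.95 for H3K4me1, 747 bp ± 17.7 for H3K4me2 and 660 bp ± 1.41 for H3K27me3 (SD, n = 2 each). Very wide domains told another order: 2093 and 1902 H3K27me3 peaks spanned 10 kb or more in replicates 1 and 2, against 34 and 52 H3K4me3 peaks. These wide domains held 21.3% ± 0.231 of the length under H3K27me3, 12.8% ± 1.18 under H3K4me1, 10.8% ± 1.72 under H3K27ac, 4.96% ± 0.0327 under H3K4me2 and 1.58% ± 0.304 under H3K4me3 (SD, n = 2 each). Marks differed in covered length (one-way F = 122, p = 0.00635) and in median width (F = 85.1, p = 0.00106, the smallest these libraries allow), both by two-sided exact permutation over all divisions of the 10 libraries into pairs. The order depended on weak peaks: with peaks of −log10 q of at least 5 only, H3K27me3 had the widest median, 4313 bp ± 382 (SD, n = 2), H3K4me3 had the narrowest, 1585 bp ± 71.4 (SD, n = 2), and the ratio of H3K4me1 to H3K4me3 covered length fell from 5.77 to 2.74. With the strongest peaks in equal number, H3K27me3 and not H3K4me1 had the highest mean covered length, 90.6 Mb ± 3.16 against 83.7 Mb ± 9.81 (SD, n = 2 each). These values overlapped within the SD.

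**Figure D1:**
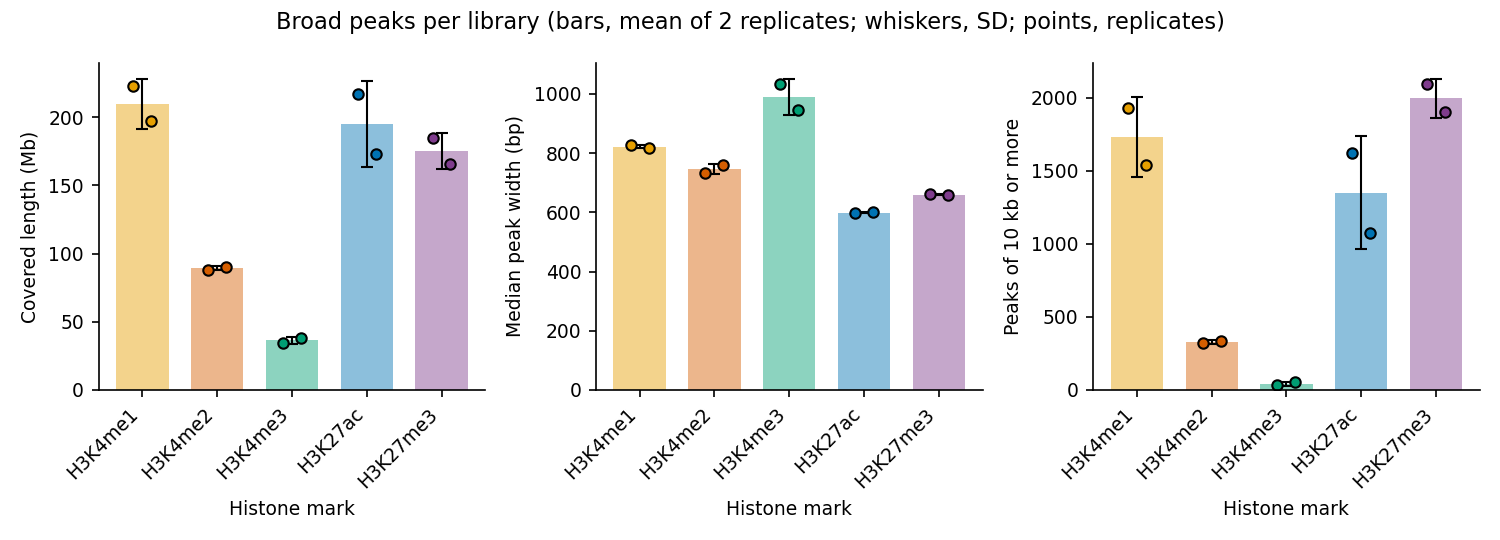
Covered length in Mb, median width in bp and number of broad peaks of 10 kb or more for each of the 5 histone marks; bars give the mean of 2 replicates, whiskers the SD and points the replicates. H3K4me3 covered 36.4 Mb with the widest median, 991 bp, and H3K27me3 had the most peaks of 10 kb or more, 2093 and 1902.

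Replicates of a mark shared more sequence than libraries of different marks. The Jaccard index, the base pairs covered in both libraries over those covered in either, was 0.748 for the H3K4me3 replicates, 0.652 for H3K4me1, 0.635 for H3K4me2, 0.526 for H3K27me3 and 0.462 for H3K27ac. The 40 pairs of libraries of different marks ranged from 0.0445 to 0.465. The mean over the 5 replicate pairs exceeded the mean over other pairs by 0.393 (one-sided exact permutation over all pairings of the libraries, p = 0.00106, the smallest possible). H3K27ac was the exception. Its replicates overlapped each other about as much as they overlapped H3K4me1, for which the mean index was 0.455, and H3K27ac replicate 2 was the only library of the 10 whose closest library, H3K4me1 replicate 2 at 0.465, carried another mark. With peaks of −log10 q of at least 5 the H3K27ac replicates reached 0.535 against a mean of 0.353 with H3K4me1. With the strongest peaks in equal number the values were 0.552 and 0.368. With narrow peaks they were 0.451 and 0.344.

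**Figure D2:**
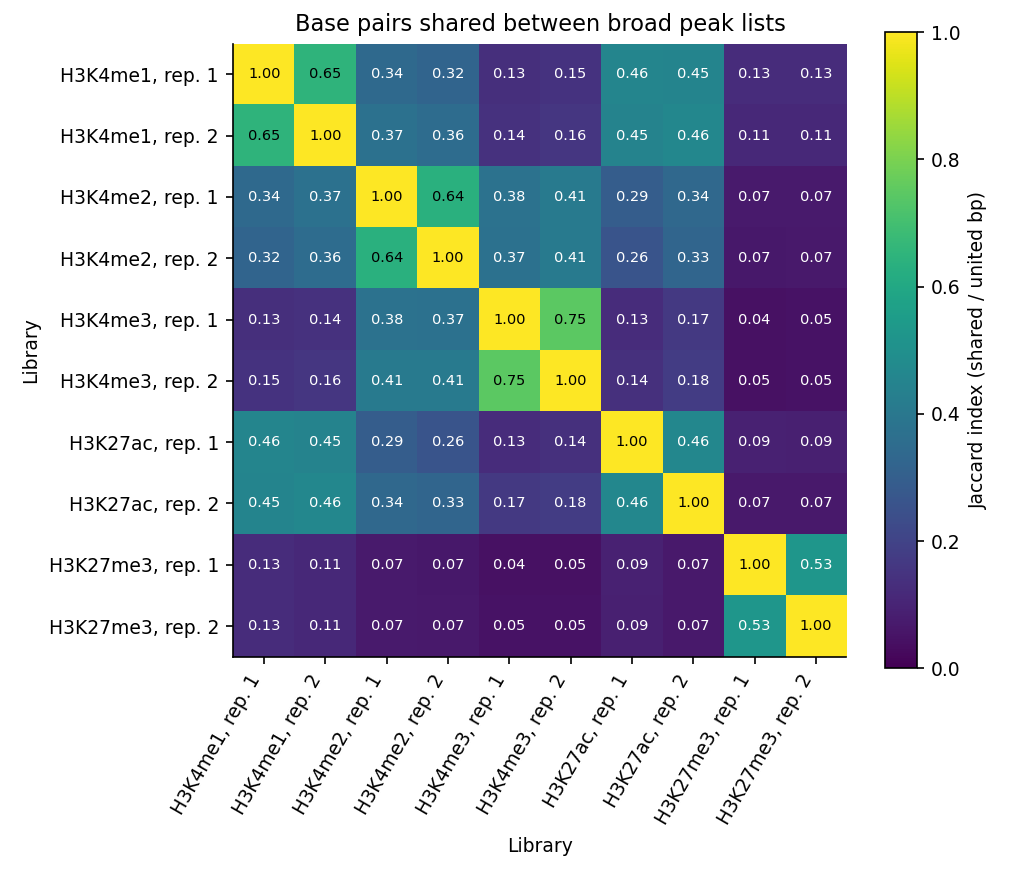
Jaccard index (shared over united base pairs of broad peaks) for every pair of the 10 libraries, on a colour scale from 0 to 1. The H3K4me3 replicates share the most, 0.748, and the H3K27ac replicates, 0.462, share about as much as H3K27ac and H3K4me1.

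The next comparison asked which marks lay in the same places. The marks of active chromatin were found together: within a replicate number, H3K4me2 and H3K4me3 shared 9.05 ± 0.291 times (SD, n = 2) as many base pairs as circular shifts of the peaks along each chromosome gave. The excess was 3.63-fold ± 0.617 for H3K4me3 with H3K27ac, 3.56-fold ± 0.184 for H3K4me1 with H3K4me2, 3.47-fold ± 0.181 for H3K4me1 with H3K4me3, 3.37-fold ± 0.403 for H3K4me2 with H3K27ac and 2.75-fold ± 0.352 for H3K4me1 with H3K27ac (SD, n = 2 each). H3K27me3 overlapped H3K4me3 1.37-fold ± 0.00857 (SD, n = 2) above expectation. H3K27ac and H3K27me3, which modify the same lysine, were the only pair below expectation, at 0.737-fold ± 0.0728 (SD, n = 2). These 8 pairs had an adjusted permutation p = 0.00125 (two-sided, 1000 circular shifts, Benjamini-Hochberg over 10 pairs), which is the smallest value reached, and each went the same way in both replicates. H3K27me3 overlapped H3K4me1 1.04-fold ± 0.0129 (SD, n = 2; adjusted permutation p = 0.0733) and H3K4me2 1.01-fold ± 0.0206 (SD, n = 2; adjusted permutation p = 1, the replicates going opposite ways), neither past the threshold of 0.05. With local shifts of 0.1 to 1 Mb, which keep regional density, both lay below expectation, at 0.972-fold ± 0.0198 (SD, n = 2; adjusted permutation p = 0.172) and 0.960-fold ± 0.0181 (SD, n = 2; adjusted permutation p = 0.0511), again not past the threshold. With peaks of −log10 q of at least 5, against shifts along the whole chromosome, they were 2.04-fold ± 0.107 and 2.35-fold ± 0.101 (SD, n = 2; adjusted permutation p = 0.00111 for each), and H3K4me3 with H3K27me3 was 2.99-fold ± 0.0646 (SD, n = 2). At the same threshold the replicates of H3K27ac with H3K27me3 went opposite ways, at 0.633-fold in replicate 1 and 1.21-fold in replicate 2, so that the depletion of this pair held for the full lists and not for the strongest peaks.

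**Figure D3:**
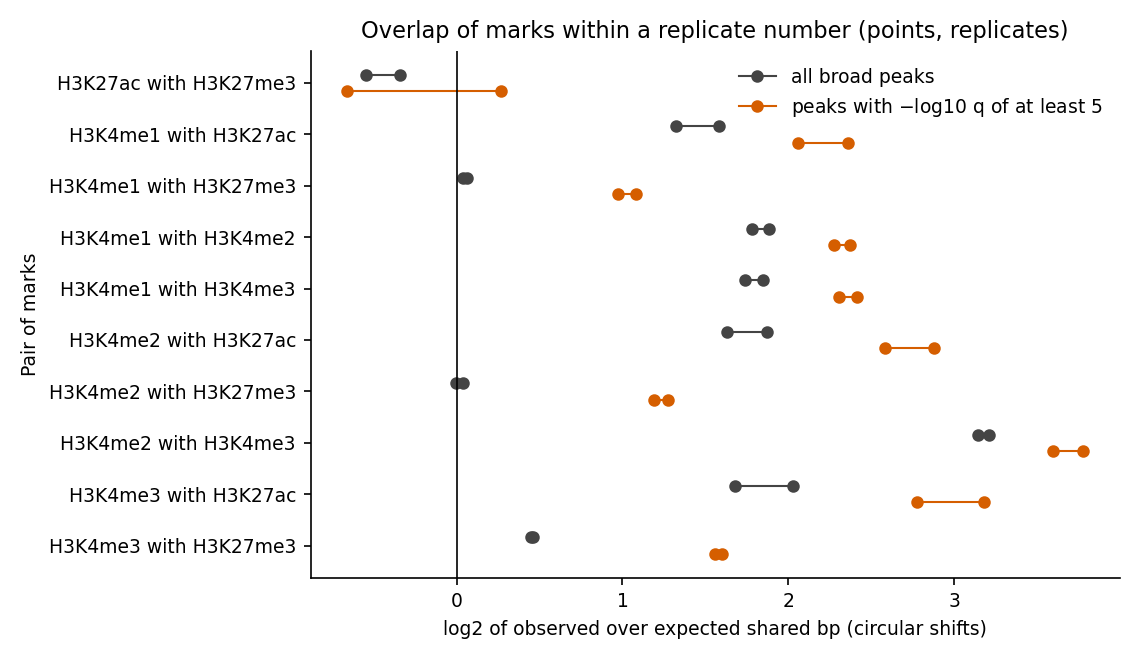
Log2 of observed over expected shared base pairs for the 10 pairs of marks, with all broad peaks in grey and with peaks of −log10 q of at least 5 in orange; each point is a replicate and a line joins the replicates. H3K4me2 with H3K4me3 lies highest, and H3K27ac with H3K27me3 lies below 0 in both replicates only with all peaks.

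In the full lists, H3K4me3 peaks, which stood in for promoters here, nearly always carried the other active marks. On assembled chromosomes, 97.1% ± 1.31 of them overlapped H3K4me1, 97.1% ± 0.631 H3K4me2 and 91.1% ± 1.22 H3K27ac (SD, n = 2 each), where shifts gave 39.6%, 19.6% and 40.5%. H3K27me3 lay on 38.5% ± 2.88 of H3K4me3 peaks (SD, n = 2) against 31.5% ± 2.19 from shifts (two-sided permutation p = 0.001 in each replicate, the smallest possible for 1000 shifts). The excess over shifts was larger with the lists of both marks limited to −log10 q of at least 5, where 32.3% ± 0.992 (SD, n = 2) of H3K4me3 peaks overlapped H3K27me3 and shifts gave 9.07%. This threshold kept 67.5% ± 5.04 of broad H3K4me3 peaks, 13.2% ± 0.412 of H3K27ac peaks and 6.92% ± 1.18 of H3K27me3 peaks (SD, n = 2 each). Most H3K27ac and H3K27me3 peaks of the full lists were thus weak calls. Sorted by the marks on lysine 27 in the full lists, 58.4% ± 1.47 of H3K4me3 peaks carried H3K27ac alone, 32.04% ± 0.00100 both marks, 5.35% ± 2.58 H3K27me3 alone and 4.17% ± 1.12 neither (SD, n = 2 each). H3K4me3 peaks with H3K27ac alone had a median width of 1110 bp ± 99.3, those with both marks 1168 bp ± 61.9, those with H3K27me3 alone 360 bp ± 62.2 and those with neither 219 bp ± 2.12 (SD, n = 2 each). An overlap of 1 bp was enough, which wider peaks reach more easily, so these widths follow in part from the sorting. Fold enrichments of the classes were not adjusted for width. Of 24180 H3K4me3 peaks in replicate 1, 21273 overlapped a peak of replicate 2, and 11554 of these carried H3K27ac alone in both replicates, 6646 both marks, 460 H3K27me3 alone and 233 neither. The other 2380 differed between replicates. Among the peaks found in both replicates the median width was 1448 bp with H3K27ac alone and 1322 bp with both marks, the opposite order. The median fold enrichment of the H3K4me3 peaks, as the authors' peak caller gave it, was 7.84 ± 0.736 for those with both marks, 5.64 ± 2.32 with H3K27ac alone, 2.24 ± 0.299 with H3K27me3 alone and 1.85 ± 0.228 with neither (SD, n = 2 each). The classes with both marks and with H3K27ac alone overlapped within the SD. Within each replicate the fold was higher with both marks, 8.36 against 7.28 in replicate 1 and 7.32 against 4.00 in replicate 2. With −log10 q of at least 5 the order of the folds turned in both replicates. Peaks with H3K27ac alone had a median fold of 15.3 ± 1.34 and a median width of 1923 bp ± 83.4, and those with both marks 13.3 ± 2.04 and 1765 bp ± 240.1 (SD, n = 2 each). Peaks with H3K27ac alone were wider in replicate 2 (1982 against 1595.5 bp) but not in replicate 1 (1864 against 1935 bp). With the lists of all 3 marks limited to −log10 q of at least 5, the share with both marks was 10.1% in replicate 1 and 20.2% in replicate 2, while the share with H3K27me3 alone was 20.3% and 11.5%. H3K27ac alone then marked 60.2% ± 2.04 and neither mark 8.80% ± 2.94 (SD, n = 2 each), so H3K27ac was less frequent than in the full lists.

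Around the summits of H3K4me3 peaks found in both replicates (17694 and 17612 summits), the marks differed in reach. A narrow H3K4me2 peak covered 98.7% ± 0.673 of summits and still 42.8% ± 1.23 of positions at 1 kb (SD, n = 2 each). H3K27ac fell from 82.4% ± 8.47 at the summit to 27.01% ± 1.19 at 1 kb and 16.2% ± 1.49 at 2 kb (SD, n = 2 each). H3K27me3 was lower at the summit, 30.6% ± 0.798, and fell to 23.6% ± 0.0254 at 0.5 kb, 22.9% ± 0.289 at 1 kb, 18.1% ± 0.105 at 2 kb and 9.01% ± 0.127 at 10 kb (SD, n = 2 each). At strong H3K27ac peaks without H3K4me3 (10777 and 4214 summits), 71.1% ± 17.5 of summits lay in a narrow H3K4me1 peak, 28.1% ± 4.39 in H3K4me2 and 3.59% ± 2.21 in H3K27me3 (SD, n = 2 each). The high values were confined to the summit. At 0.5 kb they were 19.8% ± 4.24, 8.27% ± 1.07 and 1.61% ± 0.985, and that of H3K27ac itself 22.1% ± 1.93 (SD, n = 2 each). These values describe the lists and were not tested.

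**Figure D4:**
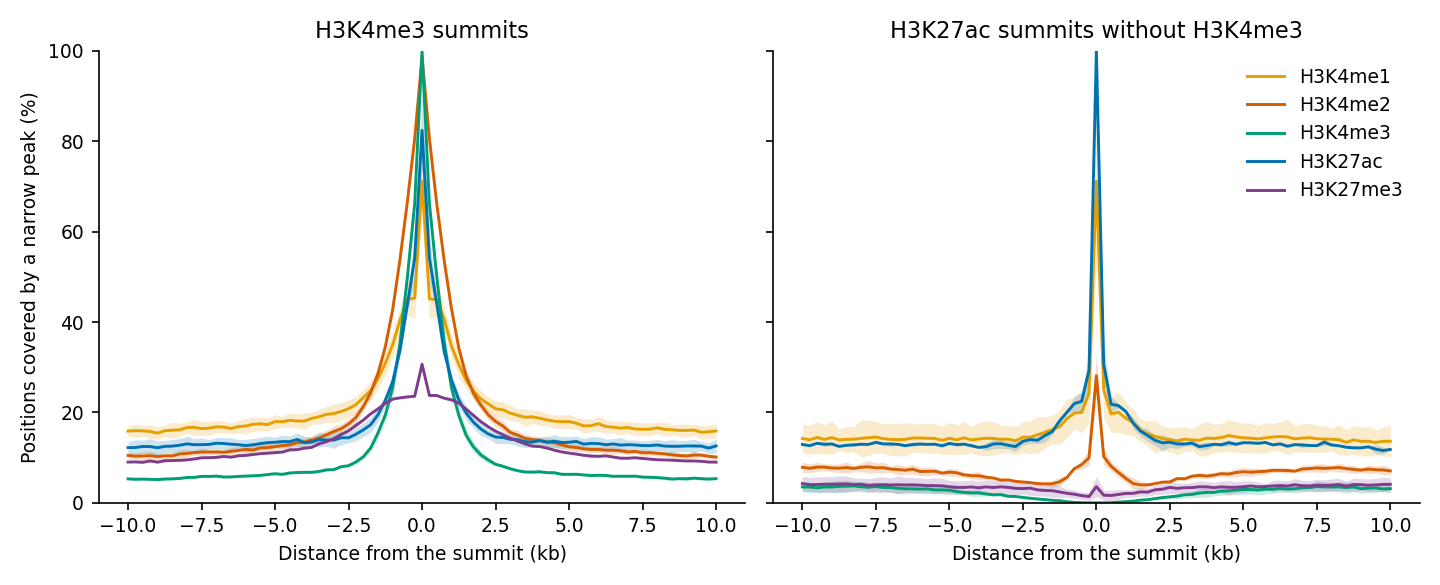
Percent of positions covered by a narrow peak of each mark against the distance in kb from H3K4me3 summits (left) and from summits of H3K27ac peaks of −log10 q of at least 5 that do not overlap H3K4me3 (right); lines give the mean of 2 replicates and bands the SD. The anchoring mark is 100% at 0 by construction, and H3K27me3 is at 22.9% at 1 kb from H3K4me3 summits.

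Distal elements were taken as H3K4me1 peaks that do not overlap H3K4me3. H3K4me1 with H3K27ac is the textbook signature of an active enhancer and H3K4me1 with H3K27me3 that of a poised one. Of the distal H3K4me1 peaks, 62.5% ± 4.06 (SD, n = 2) overlapped H3K27ac against 33.8% ± 5.20 from shifts (two-sided permutation p = 0.001 in each replicate, the smallest possible). H3K27me3 lay on 29.1% ± 2.499 (SD, n = 2), close to the 28.1% ± 2.08 from shifts. The larger permutation p of the replicates was 0.014, in a test that passed 0.05 for 10% of independent simulated sets, which lacked regional density. The shifts ran along whole chromosomes, and local shifts were not run for distal peaks. H3K27ac alone marked 46.9% ± 0.349 of distal H3K4me1 peaks, H3K27me3 alone 13.4% ± 1.09, both 15.7% ± 3.56 and neither 24.0% ± 2.82 (SD, n = 2 each). Of 114738 H3K4me1 peaks of replicate 1 that overlapped H3K4me3 of neither replicate, 79277 overlapped an H3K4me1 peak of replicate 2, and among these 31951 carried H3K27ac alone in both replicates, 4534 H3K27me3 alone, 8310 both marks and 6424 neither. The other 28058, or 35.4%, differed between replicates in the marks they carried. With peaks of −log10 q of at least 5 the overlaps were smaller, at 29.5% ± 3.44 for H3K27ac against 14.4% from shifts and 12.9% ± 1.44 for H3K27me3 against 9.39% (SD, n = 2 each; permutation p = 0.001 for both), and 59.0% ± 3.92 (SD, n = 2) carried neither.

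The widest H3K27me3 domains, ranked by their mean width in both replicates, were mostly stretches with little H3K27ac, though not all were poor in it relative to their chromosome. The domain on chromosome 23 was 214 kb ± 29.6 wide (SD, n = 2), from 3775003 to 3968091 in both replicates, and H3K27ac covered 9.58% and H3K4me3 1.74% of that shared stretch. A domain on chromosome Z, 8021205 to 8162297, was 151 kb ± 14.2 wide (SD, n = 2). The domains on chromosome 5 (35883492 to 36008033), chromosome 15 (7176643 to 7291760) and chromosome 10 (18990538 to 19091303) were 128 kb ± 4.80, 124 kb ± 13.2 and 101 kb ± 0.0219 wide (SD, n = 2 each). In 9 of the 10 widest H3K27me3 domains, H3K27ac covered between 2.62% and 22.0% of the shared stretch. The exception was chromosome 7, where 98.5 kb ± 2.44 (SD, n = 2) of H3K27me3, shared from 15753795 to 15850040, was 78.5% covered by H3K4me3, 82.7% by H3K4me2 and 75.3% by H3K27ac.

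The same locus held the widest H3K4me3 and H3K4me2 domains of these lists. A single broad H3K4me3 peak spanned 44.6 kb ± 0.248 (SD, n = 2), shared from 15784179 to 15828577 on chromosome 7, and H3K27me3 covered all of it in both replicates. Broad peaks join short gaps, and the widest narrow H3K4me3 peaks anywhere were 10140 and 12471 bp in replicates 1 and 2. Of the 10 widest H3K4me3 domains, 4 were covered by H3K27me3 over more than 50% of their length, and the other 6 over at most 25.3%. On chromosome 27 (3553114 to 3572617, 20.1 kb ± 0.204), chromosome 2 (24566730 to 24584954, 18.8 kb ± 0.770) and chromosome 13 (14926430 to 14943186, 16.8 kb ± 0.00849; SD, n = 2 each), H3K27me3 covered 100%, 94.1% and 100% of the domain. On chromosome 14 (4120250 to 4136860, 17.2 kb ± 0.903) and at another place of chromosome 13 (12417415 to 12432338, 15.0 kb ± 0.0417; SD, n = 2 each), H3K27me3 covered none of it. H3K27ac covered at least 94.6% of each of these 10 domains.

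**Figure D5:**
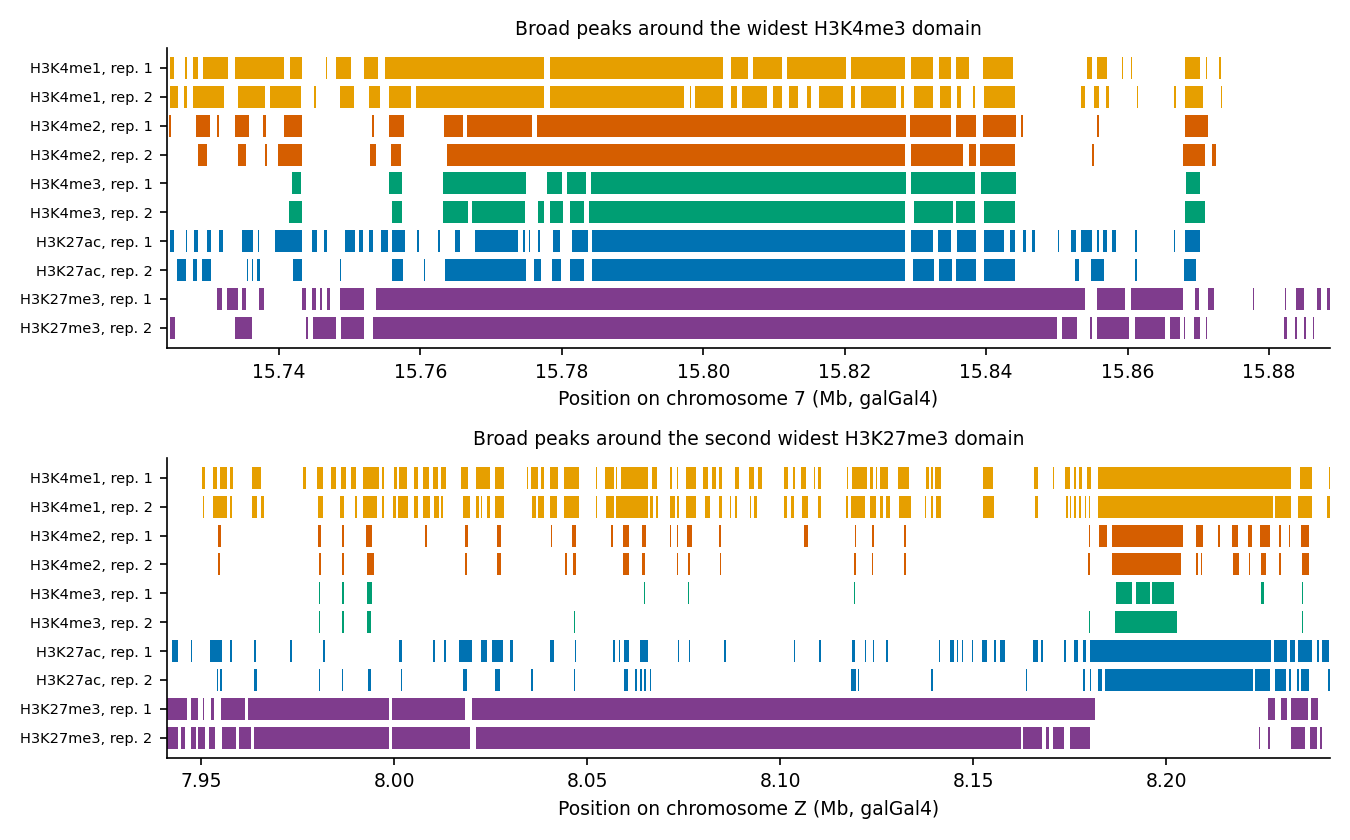
Broad peaks of the 5 marks in both replicates (rows) along chromosome 7 around the widest H3K4me3 domain and along chromosome Z around the second H3K27me3 domain, with positions in Mb (galGal4); each box is a peak. On chromosome 7 H3K4me2, H3K4me3, H3K27ac and H3K27me3 cover nearly all of the stretch from 15784179 to 15828577 and H3K4me1 84.4% of it, with gaps, while on chromosome Z the H3K27me3 domain ends beside a stretch of H3K4me1 and H3K27ac that begins near 8182300.

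Wide H3K27ac domains held little H3K27me3. The first, 72.2 kb ± 0.129 wide (SD, n = 2) on chromosome 26 from 5136154 to 5208145, was 93.1% covered by H3K4me1 and 1.04% by H3K27me3, and one on chromosome 7 from 22094150 to 22155015 (62.8 kb ± 0.575; SD, n = 2) was not covered by H3K27me3. Widths of other loci varied more: a domain on chromosome 20, shared from 5322649 to 5357336, was 64.4 kb ± 42.1 wide (SD, n = 2). Its peak ran from 5271499 to 5365700 in replicate 1. Over all H3K27ac domains of 10 kb or more (1583 and 1045 on assembled chromosomes), H3K27me3 covered 6.63% ± 0.425 of their length against 23.0% ± 1.399 from shifts of 0.1 to 1 Mb, and H3K4me1 85.3% ± 1.89 against 34.6% ± 3.27 (SD, n = 2 each; two-sided permutation p = 0.001 for both marks in each replicate, the smallest possible). H3K27me3 domains of 10 kb or more mirrored this for H3K27ac, which covered 16.5% ± 2.59 of them against 27.6% ± 4.56 from shifts, but they held more H3K4me3 than their surroundings, 7.62% ± 0.367 against 5.50% ± 0.381 (SD, n = 2 each; two-sided permutation p = 0.001 in each replicate). The excess of H3K4me3 did not pass the test for H3K27me3 domains of 20 kb or more (6.51% ± 0.0633; SD, n = 2; permutation p = 0.613). Nor did that of H3K4me1, which covered 34.6% ± 2.59 of domains of 10 kb or more against 31.2% ± 2.10 from shifts (permutation p = 0.001) and 36.5% ± 2.49 of those of 20 kb or more (SD, n = 2 each; permutation p = 0.0639). The lack of H3K27ac did not pass with narrow peaks (permutation p = 0.0859), whose lists held only 139 and 140 H3K27me3 peaks of 10 kb or more in replicates 1 and 2. The widest H3K4me1 domain lay on chromosome 17 (7334168 to 7383543 in both replicates, 80.5 kb ± 33.5; SD, n = 2) and 8 of the 10 widest of this mark lay on microchromosomes.

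Chicken chromosomes comprise large macrochromosomes and small, gene-dense microchromosomes, and all 5 marks were denser on the latter. H3K4me3 covered 6.87% ± 0.293 of microchromosomes (11 to 28) and 2.47% ± 0.249 of macrochromosomes (1 to 5 and Z; SD, n = 2 each), a ratio of 2.79 ± 0.163 (SD, n = 2). The ratio was 2.43 ± 0.330 for H3K4me2, 2.35 ± 0.0704 for H3K4me1, 2.20 ± 0.0214 for H3K27ac and 1.82 ± 0.116 for H3K27me3 (SD, n = 2 each). Microchromosomes accordingly held 34.1% ± 1.15 of the H3K4me3 length and 25.8% ± 1.07 of the H3K27me3 length (SD, n = 2 each), and the share differed between marks (F = 9.90, two-sided exact permutation p = 0.0138). This order did not hold for other peak sets. The test was not passed with narrow peaks (permutation p = 0.0804) or with the strongest peaks in equal number (permutation p = 0.0624), and with −log10 q of at least 5 the share was 38.8% ± 0.0716 for H3K27me3 and 43.8% ± 5.13 for H3K4me1 against 34.1% ± 0.682 for H3K4me3 (SD, n = 2 each).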

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

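Tests in this part were chosen after the patterns were seen. For 4 of the 6 tests of an explanation (equal lengths of the H3K27ac lists, fold on chromosome Z, coverage of Z away from H3K4me3, and local shifts at H3K4me3 peaks) the prediction was written before the tested value was computed, and for the other 2 (weak calls in either pattern) after.

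Marks differed on chromosome Z, whose covered share relative to chromosomes 1 to 5 was 0.861 ± 0.0123 for H3K4me3 (SD, n = 2) and 0.753 ± 0.0260 for H3K4me2, but 0.680 ± 0.0373 for H3K27ac, 0.640 ± 0.0536 for H3K27me3 and 0.621 ± 0.0476 for H3K4me1 (SD, n = 2 each; F = 10.4, exact permutation p = 0.0159). A lack of promoters on Z was 1 explanation considered. H3K4me3, the stand-in for promoters, was the mark least reduced on Z, at 0.861. That value is part of the pattern and no separate test. In sequence more than 10 kb from H3K4me3 peaks the ratio for H3K4me1, H3K27ac and H3K27me3 was still 0.594 ± 0.0730 (SD, n = 6 libraries). A lack of promoters had been predicted to give a value above 0.9 there, which was not met. The lower coverage was thus not confined to the surroundings of H3K4me3 peaks. The test cannot exclude the explanation, because marks more than 10 kb away may still follow promoter density. A lower copy number of Z in cultures that include female (ZW) cells may also lower calls of weak marks more than of strong ones, which predicts a higher fold at equal −log10 q. At −log10 q of 2 to 3 the median fold on Z over that on chromosomes 1 to 5 was 1.03 ± 0.0139 (SD, n = 6 libraries of those 3 marks), above 1 in 6 of 6 but between the bounds set for and against this explanation, so it stays open. The design names no group by sex, and no other explanation was tested.

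The H3K27ac replicates overlapped each other about as much as they overlapped H3K4me1 (difference of Jaccard indices 0.00717). Unequal list lengths are argued against as the whole cause: with both H3K27ac lists at the shorter length the difference was 0.0225, under the bound of 0.05. Weak calls near the threshold stay open: with peaks of −log10 q of at least 5 the difference was 0.181, but the replicate index rose by only 0.0730, and the index with H3K4me1 fell by 0.101. At the same threshold the index of the H3K4me1 replicates fell from 0.652 to 0.534, so the fall may come from H3K4me1, and with narrow peaks the index with H3K4me1 was 0.344 while that of the H3K27ac replicates, 0.451, did not rise. Differences in depth or antibody performance between the replicates also stay open and cannot be read from peak lists.

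H3K4me3 peaks with both H3K27ac and H3K27me3 are the third pattern. Chance overlap of long lists is argued against only as the whole cause. H3K27me3 lay on 36.6% ± 0.899 of the H3K4me3 peaks with H3K27ac, against 32.7% ± 1.89 from local shifts (SD, n = 2 each). The ratio was 1.12 ± 0.0373 (SD, n = 2), outside all 1000 shifts in both replicates. The excess is small, and most of the overlap is what shifts give. Weak calls could account for part of it: at −log10 q of at least 5 the share with both marks was 0.630 of its full value in replicate 2 and 0.315 in replicate 1, on either side of the bound, which leaves that explanation open. Cultures that mix cells with either mark would give the same lists, and no value here separates them.

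Sequence left out of the comparison by chromosome also carried peaks. On chromosome W, 14 H3K4me3 peaks were called in replicate 1 and 18 in replicate 2. Unplaced sequence held 4.73% ± 0.248 of the H3K4me3 length (SD, n = 2), against 1.54% ± 0.137 of the H3K27me3 length, and the fourth H3K4me3 domain by width, 17.9 kb ± 0.0134 (SD, n = 2), lay on an unplaced scaffold with no H3K27me3.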

How the results depend on the processing

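The added tests here are local shifts, the 10 kb distance from H3K4me3, and all settings of wide domains, chromosome Z and H3K4me3 peaks with H3K27me3; the others were planned. Replicate agreement, H3K4me3 peaks with H3K27me3 and both results on distal H3K4me1 peaks kept their direction and their side of 0.05 under every alternative run, as did the ratio of H3K4me1 to H3K4me3 covered length. Local shifts were not among the alternatives for these results on H3K4me3 peaks and distal H3K4me1 peaks. For H3K4me1 with H3K27me3 as a pair of marks, local shifts turned the overlap from 1.04-fold to 0.972-fold. The ratio of H3K4me3 to H3K27ac median width, 1.65, turned to 0.734 with −log10 q of at least 5 and to 0.515 with the strongest peaks in equal number. The microchromosome share of H3K4me3 minus that of H3K27me3, 8.33 percentage points, turned to −1.27 with narrow peaks (permutation p = 0.0804), −4.74 with −log10 q of at least 5 (p = 0.00529) and −0.336 with equal numbers (p = 0.0624). The number of mark pairs below expectation was 0 in place of 1 under each of these 3 settings, and the pairs above rose from 7 to 9. The cause was not tested.

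In the main permutations over libraries, replicate numbers were not taken to pair the libraries. The reason is that deviations in 10-kb bins correlated above 0.1 for 3 of 10 mark pairs (H3K4me2 with H3K27ac 0.213, H3K4me1 with H3K27ac 0.206, H3K4me2 with H3K4me3 0.128) and not for the other 7 (lowest −0.0457). Those 3 are all pairs of active marks, while the remaining pairs of active marks lay between 0.0166 and 0.0176. The check therefore neither shows nor excludes pairing by replicate number. Overlaps against shifts were measured only within a replicate number and were not repeated across numbers, so variation shared within a number could enter them. With the replicate block over 120 arrangements the ratio of covered length, 5.77 (exact permutation p = 0.00833, the smallest possible), that of median width, 1.65 (p = 0.00833), and the microchromosome difference, 8.33 (p = 0.025), kept their calls. Without replicate 1 or 2 they ran from 5.14 to 6.46, 1.58 to 1.73 and 6.76 to 9.90, with no test. Replicate agreement has no value with a replicate left out. Without replicate 2, H3K4me1 with H3K27me3 passed the threshold (adjusted permutation p = 0.00222). The chromosome Z difference kept its call with narrow peaks, −log10 q of at least 5 and equal numbers. Not run, for want of an annotation: all settings of the results on transcription start sites and gene lists. Restricting to assembled chromosomes changes nothing in shift tests and on chromosome Z, which use only these. Unknown depth limits every count and covered length.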

Other observations

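The balance of the marks on lysine 27 varied between chromosomes. The length under H3K27me3 over that under H3K27ac was 0.303 ± 0.0352 on chromosome 28, 0.389 ± 0.0293 on chromosome 25 and 0.481 ± 0.00716 on chromosome 16, but 1.27 ± 0.204 on chromosome 13, 1.18 ± 0.188 on chromosome 22 and 1.16 ± 0.122 on chromosome 7 (SD, n = 2 each). The small linkage group LGE64 had the highest ratio but an uncertain one, 2.58 ± 1.049 (SD, n = 2). These ratios were not tested, and they depend on how much was called for each mark.

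On chromosome Z the H3K27me3 domain shared from 8021205 to 8162297 was followed by an H3K4me1 domain from 8182300 to 8227499, of which H3K27ac covered 97.4% and H3K27me3 2.14%. Another H3K4me1 domain, shared from 4762899 to 4796423 on chromosome 27, was covered to 79.3% by H3K27me3 and to 56.7% by H3K27ac.

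Hypotheses on wide domains were tested after their coverage had been seen. That wide H3K27ac domains avoid H3K27me3 is consistent with a coverage 0.290 times that of local shifts, below all 1000 shifts in both replicates. That wide H3K27me3 domains hold H3K4me3 more often than their surroundings is consistent with 1.39 times the coverage of local shifts, above all shifts in both replicates, but for domains of 20 kb or more the excess did not pass the test (permutation p = 0.613), so this hypothesis stays open. Neither test identifies the promoters involved.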
